A study of Bos taurus with 9 samples.

How the data were processed

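Transcript levels were measured in longissimus dorsi, the long back muscle that gives the loin cut, of 9 Korean cattle. The animals were 3 intact bulls, 3 castrated males (steers) with high marbling and 3 steers with low marbling. Marbling is the visible fat within the muscle. Each animal had 1 array. Per the labels' protocols, total RNA from frozen muscle was amplified to biotin-labelled RNA and hybridised to a custom CombiMatrix array of bovine oligonucleotide probes, so that each array carried 1 colour and 1 animal. The scanner, the background correction, the filter on probes and the software are not given in the sources used here.

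The deposited table holds 8406 numbered probes without missing values. The series text gives 10199 genes for the array, and why the table holds fewer probes is not stated. The table's identifiers are plain numbers between 3 and 12536. None of them matched an identifier in the RefSeq gene table of the ARS-UCD2.0 assembly, which lists 37063 genes, so the values cannot be tied to genes here and probes are given by number. For this reason the 24 lists of genes (lipid metabolism, muscle fibre types, cell types and others) fixed before the data were examined could not be tested, nor could several probes of a gene be averaged.

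The authors deposited the values on a log2 scale, with each array centred near 0 (column means between -0.05 and -0.03). The log base was settled from the values. In base 2, between 84.2% and 85.5% of the 4000 lowest values of an array were whole multiples of a single intensity step, with a tolerance of 0.06, where chance gives 12%. In base e the share was between 13.7% and 16.5%. The deposited log2 values are thus logarithms of whole-number intensities shifted by 1 constant for each array. Quantile or loess normalization, which would break the whole steps, was not applied before deposit. Subtraction of a whole-number background, or a floor, would keep whole steps and cannot be excluded this way. What the constant was taken from is unknown. In 1683 probes (20.0%) the values were not whole. Of their 175 values under 60 steps, 98.3% had a whole square, where chance gives 20% at a tolerance of 0.1, as the log2 mean of 2 spots would. The other 6717 probes hold single spots, and 6 could not be placed. The table gives no background level and no detection call, so whether a dim probe lay above background is unknown, and a change in a dim probe can rest on few intensity steps.

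The deposited log2 values were tested as they are, because the arrays had already been scaled. A linear model with 1 mean for each group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 4.20 prior degrees of freedom). Contrasts were the mean of both steer groups minus bulls, high-marbled minus low-marbled steers, and each steer group minus bulls. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the 8406 probes. No filter on dim probes was used. The rule for named genes, fixed before the data were examined, needed a gene name. Its condition on size was kept, and the 2 largest rises and 2 largest falls that passed, with no overlap between steers and bulls, are given by probe number. The rule asked for more each way, and also for high-marbled against low-marbled steers, and those are not listed. Changes are log2 differences with the standard error (SE) of the model, and group values are means ± SD over 3 animals. The precision is limited by the 3 arrays in each group. The median SE was 0.37 log2 units for steers against bulls and 0.43 for the other contrasts, so the median 95% interval reached 0.82 and 0.95 log2 units to either side.

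The model was tested on simulated data with the means and spreads of the 8406 probes and 200 changed probes, in 20 simulations. Each probe had 1 spread for all groups, and all values were drawn independently. For steers against bulls, 5.35% of changes of 1 log2 unit and 73.5% of changes of 2 log2 units were recovered, and 4.08% of the calls were false. For high-marbled against low-marbled steers the shares were 1.70% and 53.7%, with 4.57% false calls. Most changes of 1 log2 unit were therefore missed by the unpaired fit in simulation. The paired fit of the steers, described below, had a median SE of 0.17 log2 units and was not simulated. On the real arrays bulls varied more than steers, and same-numbered steers deviated together. The shares of false calls thus hold under the assumptions of the model and need not hold for these arrays.

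The labels number the animals 1 to 3 in each group without saying what a number stands for. Whether same-numbered arrays deviate together from their group means was checked before fits with and without a block were compared. High-marbled and low-marbled steers of the same number correlated at 0.62, 0.73 and 0.80 for numbers 1, 2 and 3, and these were treated as pairs on the strength of the data alone. Bulls of the same number correlated with the high-marbled steers at 0.60, -0.26 and 0.29 and with the low-marbled steers at 0.67, -0.13 and 0.40, and were not treated as paired. The paired fit of the steers used their 6 arrays alone, with the number as a block. It was chosen after seeing the data, since the alternative planned beforehand put the block on all 9 arrays.

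Alternatives fixed beforehand were quantile normalization, median centring, cyclic loess, dropping the dimmest 25% of probes, an offset of 50 intensity steps, an intensity trend with robust spread, array weights, a fit on only the arrays compared, the number as a block, a threshold of 0.10, and leaving out each array. Steers differed from bulls in age as well as in castration. The labels give slaughter at 28 months for bulls and 20 months for steers, by word order alone, and castration at 6 months, so age and castration cannot be told apart. Because only the word order ties each age to a group, which group was older is not certain. The files name no slide or scan batch.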

Results

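Muscle transcript levels of 3 bulls, 3 high-marbled steers and 3 low-marbled steers were compared on 1-colour arrays, 1 animal to an array, over 8406 probes. The series asks how castration changes transcription in the longissimus dorsi of Korean cattle, and the marbling groups add a comparison within steers. Values are log2 intensities relative to the centre of each array. They ran from -8.21 to 7.53, and the SD of an array's values lay between 1.89 and 2.26. The arrays of the animals numbered 3 had the widest spread in each group, at 2.24 in high-marbled steers, 2.26 in low-marbled steers and 2.21 in bulls. Their median intensity was also the lowest of each group, at 528, 613 and 514 intensity steps, against 1098 to 2915 steps on the other 6 arrays, if a step is the same intensity on every array.

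Bull 3 differed from the other bulls more than any steer did from its group. Across probes, the 3 pairs of high-marbled steers correlated at r = 0.92 to 0.95 and the 3 pairs of low-marbled steers at r = 0.90 to 0.94, whereas bulls 1 and 2 correlated at r = 0.93 and the pairs with bull 3 at r = 0.79 and 0.87. The median SD of a probe over 3 animals was 0.60 log2 units in bulls, 0.37 in high-marbled steers and 0.44 in low-marbled steers. Steers of the same number but different marbling correlated at r = 0.96 to 0.97, above all other steer pairs. The first principal component held 44.4% of the variance and placed bulls 1 and 2 at 82.8 and 37.1, with all 6 steers between -58.9 and 7.45. The steers numbered 3 lay at -58.9 and -55.0 and the other steers between -10.3 and 7.45, so this component also parted the steers by number. Bull 3 lay at -0.55 on it, among the steers, and stood apart on the second component at 78.1, which held 25.3%. These correlations are across probes, which are not independent replicates.

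**Figure D1:**
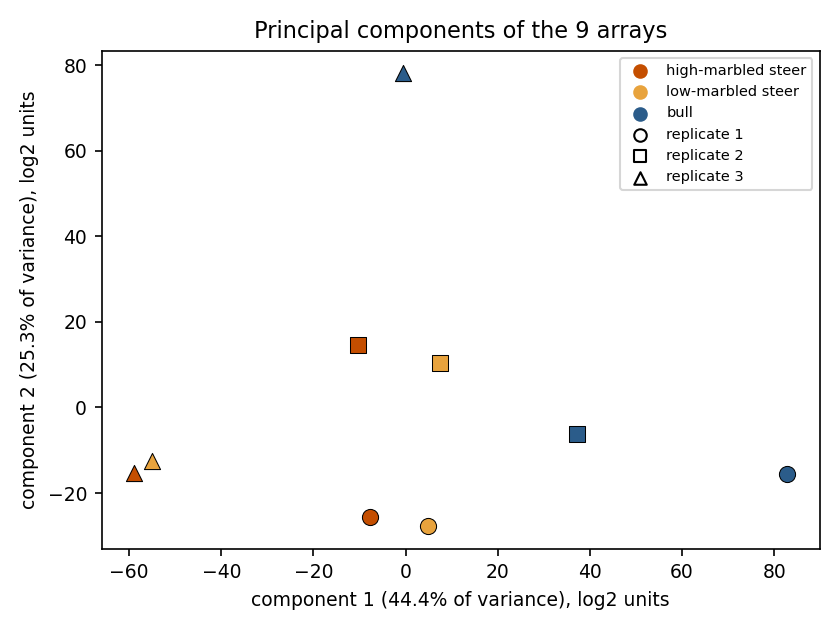
Each point is 1 array, placed by its scores on the first and second principal components of 8406 probes (log2 units), with colour for the group and shape for the replicate number. Steers of the same number lie close together, and bull 3 lies at 78.1 on the second component, far from bulls 1 and 2.

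Castrated animals differed from bulls at 411 of the 8406 probes (4.89%). Of these, 173 were higher in steers and 238 were lower. The median change of the called probes was 1.61 log2 units upward (3.05-fold) and -1.53 downward (2.89-fold), and no called probe changed by less than 0.99 log2 units. The largest rise was 3.61 and the largest fall was -4.18 log2 units. At 395 of the 411 probes no steer value overlapped a bull value, to which their selection by the test contributes. Over all probes, 1297 (15.4%) showed no overlap between the 6 steers and the 3 bulls, where chance gives 2.38%, and 785 of those were lower in steers. The probes share the same arrays and are not independent, so this share is no test.

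Among the called probes, falls were most frequent at dim probes and rises at bright ones. In the dimmest 25% of probes 117 were lower and 23 higher in steers, and in the brightest 25% 33 were lower and 61 higher. The median change of all probes moved in parallel, from -0.19 log2 units in the dimmest 25% to 0.18 in the brightest 25%. After cyclic loess, which removes such a trend with intensity, the dimmest 25% still had 81 lower and 35 higher probes, but the brightest 25% had 50 lower and 39 higher. After quantile normalization the brightest 25% had 43 lower and 76 higher, so the excess of rises there depended on the scaling.

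Probe 2776 showed the largest rise in the values as deposited. It stood at -1.07 ± 0.07 in high-marbled steers, -1.19 ± 0.69 in low-marbled steers and -4.75 ± 2.44 in bulls (mean ± SD, n = 3 each), a change of 3.61 log2 units (SE 0.83, limma adjusted p = 0.041). Bulls 1 and 3 read only 9 and 18 intensity steps there, and bull 2, at -2.18, lay close to the lowest steer, at -1.90. The size of this rise depended on such dim values. It was 2.13 log2 units with an offset of 50 steps, below the 2.99 of probe 4910. Array weights act on whole arrays, not on dim values, and gave bull 2 a weight of 6.76. With them the rise was 1.40 log2 units and was not called (adjusted p = 0.079). Over 19 settings it ranged from 1.40 to 4.90 log2 units and was not called in 9. Probe 4910, a mean of 2 spots, rose by 3.22 log2 units (SE 0.61, adjusted p = 0.025), from -1.54 ± 1.65 in bulls to 1.38 ± 0.40 in high-marbled and 1.97 ± 0.60 in low-marbled steers. Probe 1452 showed the largest fall, of -4.18 log2 units (SE 0.55, adjusted p = 0.0093). Its level was -0.88 ± 0.17 in bulls, -5.24 ± 1.33 in high-marbled steers and -4.89 ± 0.87 in low-marbled steers. In steers it read between 7 and 88 intensity steps, against 312 to 731 in bulls, so the size of the fall depends on the floor of the array, and it was -2.91 with an offset of 50 steps. Probe 2300 changed by -3.45 log2 units (SE 0.51, adjusted p = 0.015) and stood at -0.43 ± 0.26 in bulls, -2.31 ± 0.76 in low-marbled steers and -5.44 ± 1.21 in high-marbled steers. Its difference of -1.88 between low-marbled steers and bulls did not pass (adjusted p = 0.17). Its change was -2.70 with an offset of 50 steps. Its difference between high-marbled and low-marbled steers was -3.14. That did not pass the unpaired test (SE 0.59, adjusted p = 0.30) and passed when steers were paired by number (SE 0.34, adjusted p = 0.031). High-marbled steers read only 25 to 33 intensity steps at this probe, against 180 to 270 in low-marbled steers. The size of this difference therefore depends on the floor of the array.

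**Figure D2:**
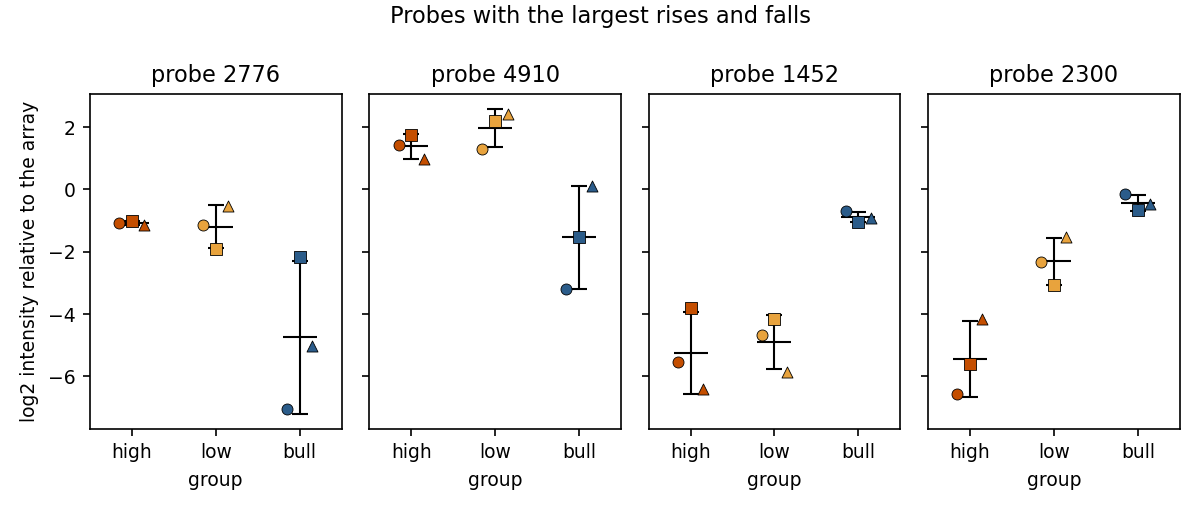
Log2 intensity relative to the array of 4 probes in each animal, with horizontal bars for the group mean and error bars for the SD over 3 animals. Shapes give the replicate number as circle 1, square 2 and triangle 3. Probes 2776 and 4910 were higher and probes 1452 and 2300 lower in steers than in bulls, and the bulls spread widely at the first pair.

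Single animals weighed heavily on the number of called probes. Without bull 1 the count was 31, without bull 2 it was 306 and without bull 3 it was 920. Leaving out high-marbled steers 1, 2 and 3 gave 54, 155 and 92, and leaving out low-marbled steers 1, 2 and 3 gave 112, 179 and 85. The excess of falls over rises was not stable either. There were 535 rises and 385 falls without bull 3, 184 and 122 without bull 2, and 7 and 24 without bull 1, and a fit of only 2 groups, steers and bulls, gave 252 rises and 229 falls with all bulls kept. With the dimmest 25% of probes dropped, 203 probes were called, 107 higher and 96 lower. Other planned settings raised the count. It was 1615 with the number as a block over all arrays, 613 higher and 1002 lower. With array weights, whose estimate did not converge, it was 2508, 1219 higher and 1289 lower.

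High-marbled steers compared with bulls gave 318 called probes, 86 higher and 232 lower, with a median rise of 1.88 and a median fall of -1.95 log2 units. Low-marbled steers compared with bulls gave 0 called probes in limma (smallest adjusted p = 0.077), although 1442 probes had an unadjusted value under 0.05, where 420.3 would by chance. The 420.3 assumes 1 spread for all groups, whereas bulls varied more than steers, and probes are not independent. The excess over it is therefore no test. The gap between 318 and 0 called probes is no test of a difference between the steer groups, which is given directly below. Across all probes the changes of both steer groups from bulls correlated at r = 0.85 and had the same sign at 84.4% of probes. Both comparisons use the same 3 bulls, and unchanged groups simulated against such bulls gave r = 0.65 (range 0.63 to 0.68 in 100 simulations) and the same sign at 72.6%. The covariance was 0.53 against 0.21 in the simulation, a difference of 0.33. The simulation leaves out that same-numbered steers of both groups deviate together, at correlations of 0.62, 0.73 and 0.80, which by itself raises r. It also draws every probe independently. Its range of r is therefore narrower than arrays whose probes vary together would give, and cannot show how far 0.85 lies from unchanged groups. The bulls were not split between the comparisons, since 1 part would hold a single bull, so part of the excess in r may also come from sharing them. The excess of falls in high-marbled steers was lost without bull 3, with 427 rises and 404 falls, and shrank without bull 2, with 108 rises and 126 falls. The count was 84, 234 and 831 without bulls 1, 2 and 3, 34, 90 and 29 without high-marbled steers 1, 2 and 3, and 105, 156 and 290 without low-marbled steers 1, 2 and 3. It was 61 when only the 6 arrays compared were fitted, 802 at a threshold of 0.10, 1381 with the number as a block and 2165 with array weights. For low-marbled steers it was 5 without bull 3, 0 without any other array and 1086 with array weights, whose estimate did not converge.

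**Figure D3:**
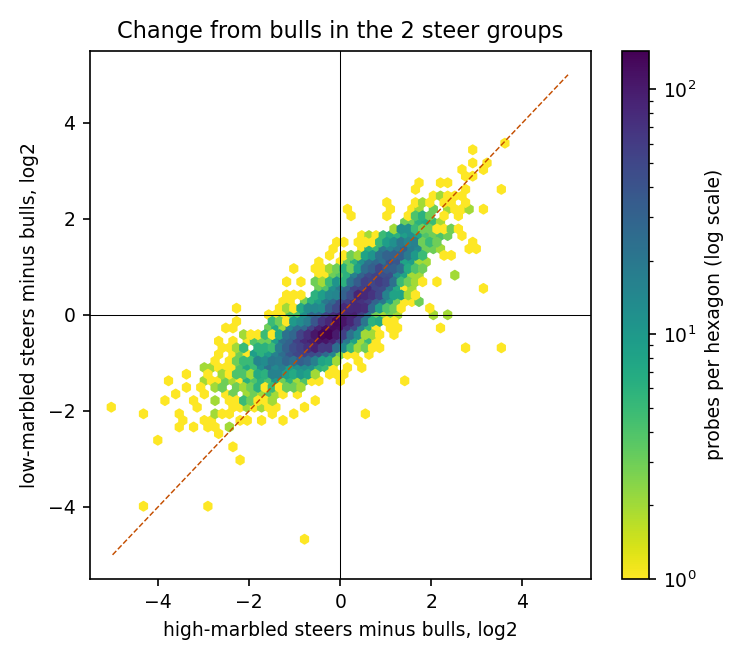
Log2 change from bulls of 8406 probes in high-marbled steers (horizontal axis) and low-marbled steers (vertical axis), with colour for the number of probes in a hexagon on a log scale and a dashed line where both changes are equal. The changes correlate at r = 0.85, against 0.65 for simulated unchanged groups that share the bulls, with every probe and array drawn independently.

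The unpaired comparison of high-marbled and low-marbled steers called 0 probes (limma, smallest adjusted p = 0.072, 329 with an unadjusted value under 0.05 against 420.3 by chance). Its spread was pooled with that of bulls, whose median SD was 0.60 log2 units against 0.37 in high-marbled and 0.44 in low-marbled steers. When only the steer arrays were fitted, unpaired, 492 probes had an unadjusted value under 0.05 and 0 were called. Whether the unadjusted count lay below or above chance thus depended on the arrays fitted. In the fit of all 9 arrays, array weights, whose estimate did not converge, gave 60 called probes (22 higher and 38 lower). Leaving out high-marbled steer 1 gave 3. The median absolute difference was 0.26 log2 units, compared with 0.50 between steers and bulls. Both medians include noise, which differs between them. The more variable bulls entered only the second, and deviations shared by same-numbered steers cancel only in the first. The 2 medians therefore do not compare sizes of effect. When the steers were paired by their number, 194 probes were called (2.31%), 57 higher and 137 lower in high-marbled steers, with 2223 at an unadjusted value under 0.05. The median rise among them was 1.15 log2 units (2.22-fold) and the median fall -1.23 (2.34-fold), and the smallest adjusted p was 0.018. All 194 moved in the same direction in 3 of 3 pairs, which their selection by a paired test on these same pairs makes nearly certain. Over all probes 4229 (50.3%) did so, where chance gives 25%, with 2266 higher and 1963 lower in high-marbled steers. All probes share the same 3 pairs and are not independent, so this share is no test. The called probes were mainly dim ones, with 114 in the dimmest 25% of all probes and 5 in the brightest 25%. With the dimmest 25% of probes dropped, 2 probes were called in the paired fit, and leaving out pairs 1, 2 and 3 in turn gave 298, 0 and 45. The pairing was read from the arrays themselves and is not stated in the labels. With the number as a block over all 9 arrays, 0 probes were called between the steer groups.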

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

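Under quantile normalization, median centring, cyclic loess, an offset of 50 steps, an intensity trend with robust spread, and single-spot probes alone (chosen after seeing the data), the count for steers against bulls stayed between 355 and 508, that for high-marbled steers against bulls between 266 and 400, and both other counts stayed at 0. With the dimmest 25% dropped, the counts were 203 for steers against bulls and 102 for high-marbled steers against bulls. Array weights, whose estimate did not converge and gave bull 2 a weight of 6.76 and bull 3 one of 0.19, raised the counts to 2508 for steers against bulls, 2165 for high-marbled and 1086 for low-marbled steers against bulls, and 60 between the steer groups. A fit of only the arrays compared gave 61 for high-marbled steers against bulls. With the replicate block over all arrays the counts against bulls were 1615 for all steers, 1381 for high-marbled and 240 for low-marbled steers, and all 411 probes of the unblocked fit were among the 1615, although same-numbered bulls and steers did not all deviate together, bull 2 being the exception. At a threshold of 0.10 the counts were 1074, 802 and 72 in that order, and 1 between the steer groups. The paired fit of the 6 steers alone (replicate block, chosen after seeing the data) called 194 probes, 194 after quantile normalization, 2 without the dimmest 25%, and 298, 0 and 45 without pairs 1, 2 and 3. Leaving out each array gave 31 to 920 for steers against bulls, 29 to 831 for high-marbled steers against bulls, 0 to 5 for low-marbled steers against bulls and 0 to 3 between the steer groups, where the 3 came without high-marbled steer 1. It gave r = 0.78 to 0.90 for the changes of both steer groups. The cause of these differences was not tested, except that fewer arrays and a looser threshold change counts by construction. The 4 probes kept their direction under every setting in which each was tested, and passed in 62 of 76 probe and setting combinations. These include the threshold of 0.10, which repeats the main fit at a looser limit. All 4 had been picked as called probes with no overlap between steers and bulls. Leaving out an array, array weights and other fits of the same values therefore could not reverse them. Their kept direction is no independent support in those settings. Probes 1452, 2300 and 2776 lay in the dimmest 25%, so the fit without those probes could not test them. Probe 4910 was not among the single-spot probes. Probe 2776 passed in 10 of 19 and probe 1452 in 19 of 19, with adjusted p between 1.6e-04 and 0.13 over all 4. The tests of gene lists and the mean of a gene's probes were not run, because the probes carry no gene names here. Signal over background was not given, so a limit from detection cannot be stated.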

Other observations

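Among the tests below, the 84 splits of the 9 arrays, the unpaired splits of 6 arrays and the comparison of probes with 1 and 2 spots were set out before their results were seen, and the others, the 27 splits within numbers among them, were chosen afterwards. The difference between steers and bulls was compared with other groupings of the same arrays. In a fit with 2 groups the real split called 481 probes. Of the 84 splits into 6 and 3 arrays, 2 called as many, the real one included. That share would exclude chance only if the 9 arrays were exchangeable. Steers of the same number deviated together, at correlations of 0.62, 0.73 and 0.80, so the arrays were not exchangeable and chance is not excluded by these splits. The median of the other splits was 0. The split that called more than the real one, at 737 probes, set the 3 animals numbered 3 against all others. The same splits for numbers 1 and 2 called 0 probes each. The arrays numbered 3 thus stand apart from the rest at more probes than steers do from bulls in this fit. There were 27 splits with 1 array of each number on the smaller side. Among these 27, only the real one called 481 probes, against 3 at the highest other. These are among the 84 and were picked after all their counts had been seen, so they add no independent test. A different spread of values between arrays is argued against, since 93.9% of the 411 probes were still called after quantile normalization, and noise of dim probes cannot be the whole cause, since 43.1% of the calls lay in the brightest 50% of the probes. Castration and age stay open as explanations and cannot be told apart, because 0 of the bulls share an age with a steer in the labels.

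The other comparisons have too few splits for a share under 0.05. For high-marbled steers against bulls, only the real one of the 10 splits called probes, with 61 against 0 at the highest other. For low-marbled steers against bulls and for the unpaired steer groups, all 10 splits called 0. Of the 4 splits that part all 3 steer pairs, only the real one called probes, with 194 against 0 at the highest other.

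Steers of the same number deviated together from their group means, with correlations of 0.62, 0.73 and 0.80. A candidate explanation is that arrays of a number were processed together in all 3 groups. It predicts that the spread of the array values follows the number, and that spread was highest at number 3 in every group, but the exact permutation test over 216 relabellings gave p = 0.11 (the smallest it can give is 0.028), so this could not be decided. Bulls 1 and 3 deviated with the high-marbled and low-marbled steers of their number, at 0.60 and 0.67 for bull 1 and 0.29 and 0.40 for bull 3, and bull 2 did not, at -0.26 and -0.13. Shared kinship, feeding or slaughter day of same-numbered steers was not tested, because the labels name none of these.

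The 1683 probes averaged over 2 spots allow a look at noise between spots on an array. If that noise made up the spread between animals, averaging would lower the residual SD to 0.71 of that of single-spot probes. The ratio was 0.95 at matched level. The median SD was 0.52 against 0.55. The 0.52 lay between the lowest and highest medians of 1000 matched draws of single-spot probes (0.517 and 0.571), but near the lowest. Noise between spots is therefore argued against as the main source of the spread, provided that both kinds of probe vary alike otherwise. The limit set beforehand was 0.95, which the ratio passed by little, so a small part of the spread from this noise is not excluded. Steers and bulls differed at 3.68% of the 2-spot probes and at 5.18% of the single-spot probes. Whether animals, RNA or hybridisation carry the rest was not tested.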
